A study of Rattus norvegicus with 25 samples.

How the data were processed

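Small RNA sequencing of mitochondria from rat red gastrocnemius was analysed in 25 libraries, 13 from endurance-trained and 12 from sedentary rats. Groups were taken from the sample labels. Per the labels' protocols, mitochondria were isolated from about 100 mg of muscle with a magnetic bead kit made for mouse tissue, incubated with 312 µg of RNase A for 1 h at 37 °C, and washed after proteinase K. Libraries were made with a NEBNext small RNA kit with adapters at 0.3 of their usual strength and 20 PCR cycles. The labels' protocols name no molecular identifiers, so counts are of reads, not of molecules.

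The authors deposited a table of raw counts, whole numbers per mature miRNA with empty cells where the normalized table has 0, which were read as 0. The authors also deposited a table of normalized values, a signal equal to the raw count divided by 1 size factor per library. The ratio of both tables was constant within each column to a relative deviation of 1.12e-09, and size factors computed here with DESeq2 differed from it by at most 4.75e-06. The submitters' processing notes name fastp 0.20.0 and DESeq2 1.36. The aligner, the counting tool, its strand setting, its treatment of reads that match several miRNAs, the genome build and the miRNA annotation are not given in the sources used here. No coordinates are printed for that reason. The RefSeq gene table of the rat assembly GRCr8 held a precursor for 753 of the 764 rows and was used for names and for which precursors overlap.

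Total counts ranged from 12181 to 202388 per library. All pairs of libraries within a group differed by far more than sampling noise (lowest chi-square per degree of freedom 21.1 over 144 pairs), so none was a copy of another in its group. Trained libraries were not compared with sedentary ones in this way. Each library was counted as 1 replicate by its own title number. Independence of litter or batch could not be checked, since the labels give neither. Where a share is 0, the limit given is 3 counts of the total.

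The main test was the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) on raw counts with TMM factors, trained minus sedentary, without covariates. filterByExpr (minimum count 10, minimum total 15) kept 76 rows holding 96.9% to 99.0% of counts. P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. Lists with at least 3 tested members, 8 of 17, were tested with camera (limma 3.58.1, preset correlation 0.01, and an estimated correlation) and fry. Whole profiles were compared with a permutational test written for this purpose, on Euclidean distances of log2 CPM. For an alternative setting, vegan 2.7.1 gave Bray-Curtis distances of CPM. 23 measures of library composition were compared with two-sided permutation tests of 100000 resamples, also written for this purpose (numpy 2.4.6). These tests, the lists and the naming rule were fixed before the data were examined.

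The lists were muscle-enriched miRNAs, miRNAs described in mitochondria, miRNAs described as responding to endurance exercise, markers of erythrocytes, leukocytes, endothelium, smooth muscle, fibroblasts and connective tissue, and of liver, brain and pancreas, the let-7, miR-29, miR-30 and miR-181 families, the miR-23, miR-24 and miR-27 clusters, miR-17~92 and its paralogs, the Dlk1-Dio3 cluster, and the miR-200 family with epithelial miRNAs. Named miRNAs were those past the threshold, filled up to 20 in order of p and reported as not passing, the 10 most abundant, every tested member of the muscle and mitochondrial lists, and the 2 most abundant tested members of each other list. This gave 46. miRNAs printed for their absence or low count, miR-106b-3p with its cluster, and miR-150-3p were chosen after their values were seen.

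Alternatives were DESeq2 1.42.0, limma-voom, limma-trend on the authors' normalized values with pseudocounts of 1 and 0.5, other scalings and filters, leaving out the most abundant miRNA, robust dispersion, covariates (total count, title number, and 1 surrogate variable from sva 3.50.0), leaving out the 1 library with a total under 0.25 of the median, and leaving out each library. 3 alternatives were added after seeing the data. They counted near-identical rows once, tested rats numbered up to 13 and above 13 apart, and tested detection at 10 or more counts. Detection was tested with Fisher's exact test (scipy 1.17.1). Whether the group difference changed with the title number was also tested after seeing the data. Rows were called near-identical when they differed by at most 10% in every library where the pair summed to at least 10 counts, in at least 3 libraries, among rows with at least 100 counts.

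The tests were tried on simulated data. In each data set of miRNA counts, 24 of the 76 miRNAs were altered together, by 2-, 4- or 8-fold. Over 20 negative binomial data sets with the means and library sizes of the 76 miRNAs, 10.6%, 57.5% and 86.3% of 2-, 4- and 8-fold changes were recovered (160 of each), and 5 of 1040 unchanged miRNAs were called. On real counts with the group labels permuted, the recovered shares were 28.8%, 51.3% and 76.3%, and 10 of 1040 unchanged miRNAs were called. The permutation test found 20 of 20 shifted measures and 10 of 180 unshifted ones at a p under 0.05.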

Results

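Small RNA was sequenced from mitochondria isolated from the red part of the gastrocnemius, a hindlimb muscle rich in oxidative fibres, of male Wistar-Kyoto rats. 13 rats had run on a treadmill on 5 days a week for 4 weeks, and 12 sedentary rats had spent the same time on a treadmill that did not move. Each library came from 1 rat, and libraries are named by their group and the number in their title. The mitochondria had been treated with RNase A before lysis, which digests RNA outside the organelle. Total miRNA counts per library ranged from 26793 to 202388 in the trained group (87754 ± 61994, SD, n = 13) and from 12181 to 186006 in the sedentary group (79497 ± 45121, SD, n = 12). The difference in means did not pass the threshold (two-sided permutation test, p = 0.706, adjusted p = 0.773 over 23 measures). Of the 764 rat mature miRNAs listed, 260 had at least 1 count in some library and 40 had a count in all 25 libraries.

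**Figure D1:**
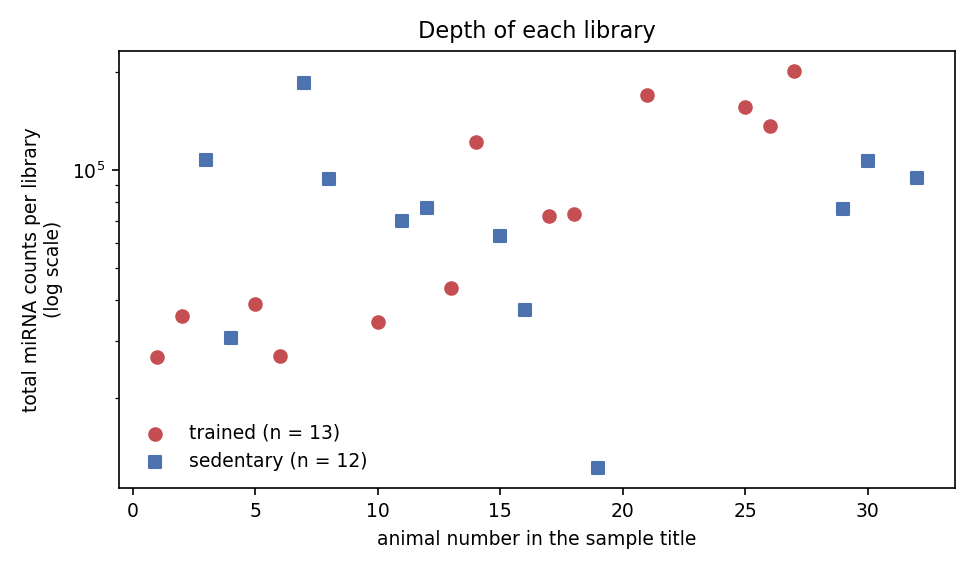
Total miRNA counts per library (log scale) against the number in the sample title, for 13 trained (circles) and 12 sedentary (squares) rats. Trained libraries numbered 1 to 13 lay between 26793 and 43510 counts and those numbered 14 to 27 between 72553 and 202388.

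The first question was which miRNAs the mitochondrial preparations held. miR-1-3p, a muscle-specific miRNA that acts in myoblast differentiation, was the most abundant, with 10.6% ± 4.13 of counts (SD, n = 25). miR-1b followed with 8.28% ± 2.40, miR-206-3p, which is restricted to skeletal muscle, with 7.56% ± 3.69, and miR-378a-3p, encoded within the gene of the metabolic coactivator PGC-1β, with 6.78% ± 2.42 (SD, n = 25). let-7i-5p held 3.92% ± 1.13, miR-143-3p 2.72% ± 1.28, miR-148a-3p 2.61% ± 1.28 and miR-486 2.60% ± 1.24 (SD, n = 25). In each library the 10 most abundant entries together took 70.9% ± 7.48 of counts in trained rats (SD, n = 13) and 65.8% ± 8.34 in sedentary rats (SD, n = 12; permutation test, p = 0.123, adjusted p = 0.410). miR-133a-3p, another muscle-enriched miRNA, held 0.237% ± 0.252 (SD, n = 25) and reached 10 counts in 19 of 25 libraries. The cardiac and slow-muscle miRNA miR-499-5p had a count in 5 libraries, and miR-208a and miR-208b had 0 of 2094773 counts over all libraries, which allows up to 1.43 CPM (CPM, the count relative to the library total). miR-34a-5p, miR-181c-5p, miR-338-3p and miR-494-3p, all described in mitochondria of other tissues, also had 0 counts. Such limits cover counting error only. miR-16-5p and miR-29a-3p, found in most tissues, had a count in 1 library each. Whether entries were filtered, or reads with several matches removed, before the counts were made is not given in the sources used here, so a 0 is a value of the table and does not show absence from mitochondria. In a single library, 0 counts allowed between 14.8 and 246 CPM. None of the 25 libraries came from whole muscle or from mitochondria without RNase A. A count therefore does not show that a miRNA lay inside mitochondria either.

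Several abundant entries carried nearly the same counts as another entry and are reported as uncertain. miR-3571 had 241335 counts over all libraries and miR-1-3p 241423, and their annotated precursors overlap. miR-3557-5p had 137458 counts and miR-378a-3p 136920, also with overlapping precursors. miR-133a-3p and miR-133c both had 3645 counts and miR-133b-3p 3632. In all, 17 such pairs were found, and the 16 duplicate entries among them held 21.0% ± 2.87 of counts (SD, n = 25). miR-378b, with 132331 counts, stayed within 10.6% of miR-378a-3p in every library, just outside the 10% tolerance. miR-107-3p matched miR-103-3p in most libraries, but was at 800 against 953 CPM in trained library 1, also outside the tolerance.

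**Figure D2:**
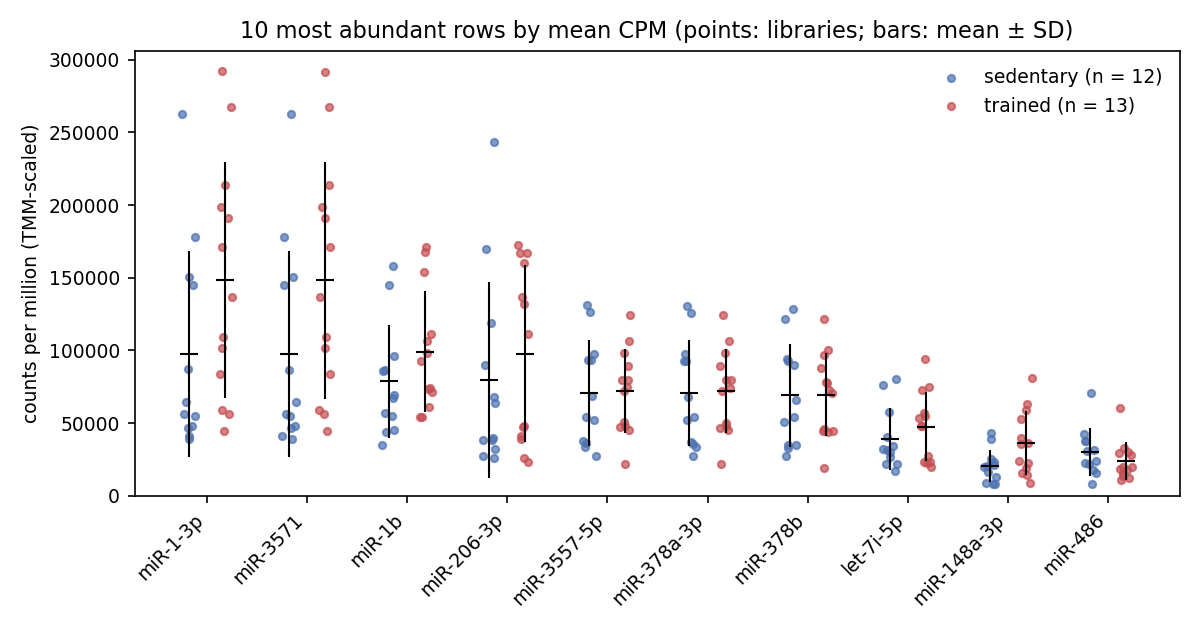
CPM, counts scaled to the library total and by the trimmed mean of M-values (TMM), of the 10 entries with the highest mean over all libraries, in 12 sedentary and 13 trained rats. Points are libraries and bars the mean ± SD; the groups overlapped for each entry, and miR-3571 and miR-3557-5p mirrored miR-1-3p and miR-378a-3p.

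The main comparison asked which miRNAs of the mitochondrial preparations differed after 4 weeks of endurance training. None of the 76 miRNAs with enough counts passed the test (edgeR quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p under 0.05). 1 of them had an unadjusted p under 0.05 with edgeR. DESeq2, which tested a wider set of 260 miRNAs, had 8, and limma-voom had 14 of the 76. Both also called 0. The miRNA under 0.05 with edgeR was miR-148a-3p, at 36220 ± 22088 CPM in trained rats (SD, n = 13) and 20513 ± 11271 in sedentary rats (SD, n = 12). Its log2 fold change was 0.82 (SE 0.32, p = 0.0128, edgeR adjusted p = 0.916). When the rats were taken apart by number, at a boundary chosen after the totals were seen, the value among those numbered 1 to 13 was -0.03 (SE 0.35, 6 trained and 6 sedentary, edgeR p = 0.925), and among those numbered 14 to 32 it was 1.25 (SE 0.43, 7 trained and 6 sedentary, edgeR p = 0.00374). In a single joint fit of all 25 libraries, the term for a change of the group difference between these ranges was 1.47 (SE 0.54, edgeR p = 0.00898, adjusted p = 0.227). Depth differed between the groups in opposite directions in these ranges. Totals at numbers 1 to 13 were 26793 to 43510 in trained and 30527 to 186006 in sedentary rats. At numbers 14 to 32 they were 72553 to 202388 in trained and 12181 to 106661 in sedentary rats. A change with number can therefore not be told apart from a change with depth.

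Muscle and mitochondrial miRNAs did not pass the test either. miR-1-3p had a log2 fold change of 0.60 (SE 0.36, 95% interval -0.12 to 1.32, edgeR adjusted p = 0.916), with 148197 ± 81282 CPM in trained (SD, n = 13) and 97755 ± 70858 in sedentary rats (SD, n = 12). It passed the threshold without a filter on low counts, at 0.73 with edgeR adjusted p = 0.00758, a setting that called 66 miRNAs. Chance is not excluded, since 9 of 100 groupings of the rats, the real one included, called at least 2 of the tested miRNAs. In the main test the values for miR-1b and miR-206-3p were 0.33 (SE 0.30) and 0.30 (SE 0.38). For miR-378a-3p the value was 0.02 (SE 0.30, 95% interval -0.58 to 0.63), and it was -0.15 when scaled by total counts alone. For miR-486, which both muscle and red cells express, it was -0.34 (SE 0.29). Of the 16 muscle-enriched miRNAs listed before the data were examined, 8 had a count, 6 were tested and 0 passed, over all miRNAs or adjusted over the list alone (lowest adjusted p = 0.596). 5 of the 6 had positive values, 3 of them the miR-133 entries that share counts and turned negative under 4 other settings and among rats numbered 14 to 32 (camera adjusted p = 0.298, and adjusted p = 0.530 with an estimated correlation). The mitochondrial list had 18 miRNAs, of which 14 had a count and 10 were tested. As scaled here 5 were positive and 5 negative, and 0 passed, also adjusted over the list alone (lowest adjusted p = 0.981, camera adjusted p = 0.898). Among them, let-7b-5p was at 0.0075 (SE 0.31), miR-26a-5p at 0.21 (SE 0.37) and miR-21-5p at -1.25 (SE 1.04). The list of miRNAs described as responding to endurance exercise had 6 tested members, 5 positive and 1 negative, and 0 passed (lowest adjusted p = 0.596 adjusted over the list alone, camera adjusted p = 0.298). The positive members included miR-133a-3p and miR-133b-3p, which share counts, and miR-378a-3p at 0.02.

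**Figure D3:**
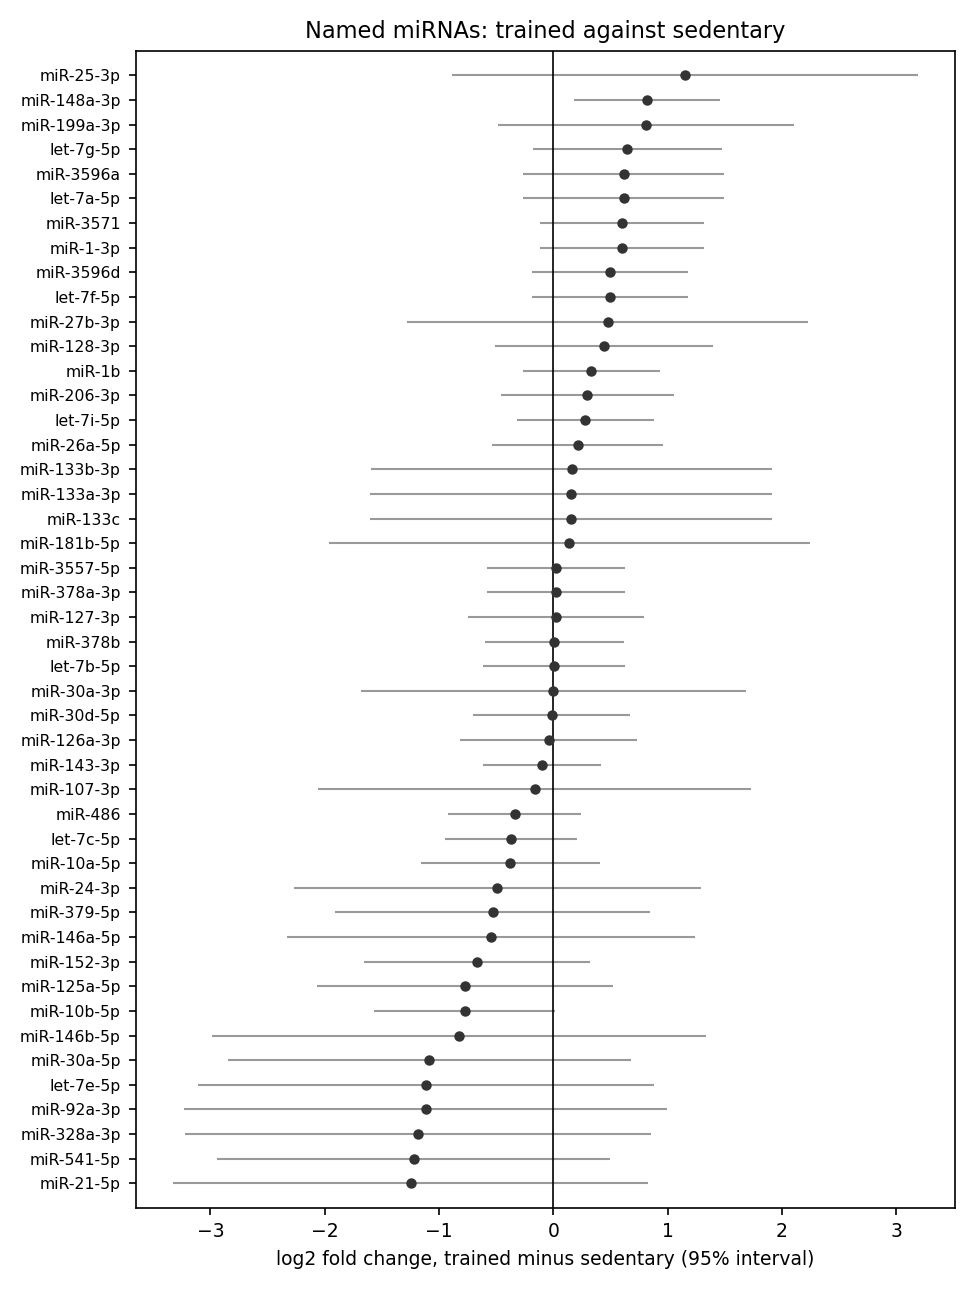
Log2 fold change, trained minus sedentary, of the 46 named miRNAs with the 95% interval of the edgeR fit (13 trained and 12 sedentary rats). The interval of miR-148a-3p, 0.18 to 1.46, lies above 0, and no miRNA passed after adjustment.

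MiRNA families were described in the same way. Of the let-7 and miR-98 family, which restrains proliferation and acts on insulin signalling, 8 members were tested, 5 positive and 3 negative, and 0 passed (camera adjusted p = 0.298, lowest adjusted p = 0.414 adjusted over the list alone). let-7g-5p was at 0.65 (SE 0.41), let-7f-5p at 0.49 (SE 0.34) and let-7c-5p at -0.37 (SE 0.29). The family took 10.1% ± 2.50 of counts in trained (SD, n = 13) and 10.1% ± 1.93 in sedentary rats (SD, n = 12). From the Dlk1-Dio3 imprinted cluster, a large set of miRNAs active in developing and regenerating muscle, 28 of 84 entries had a count and 5 were tested, 2 positive and 3 negative, with 0 passing (camera adjusted p = 0.298, lowest adjusted p = 0.741 adjusted over the list alone). miR-127-3p of this cluster was at 0.021 (SE 0.38), miR-379-5p at -0.53 (SE 0.69) and miR-541-5p at -1.22 (SE 0.86). In the miR-30 family, 5 members were tested, 1 positive and 4 negative, and 0 passed (camera adjusted p = 0.648, lowest adjusted p = 0.999 adjusted over the list alone). miR-30d-5p was at -0.015 (SE 0.34) and miR-30a-5p at -1.08 (SE 0.88). Other families had fewer than 3 tested members and no list test. They took 0.0919% of counts in trained and 0.0947% in sedentary rats for the miR-181 family, 0.340% and 0.434% for the miR-23, miR-24 and miR-27 clusters, and 0.233% and 0.378% for miR-17~92 and its paralogs. The shares were 0.00995% ± 0.0185 and 0.0291% ± 0.0452 for the miR-200 and epithelial list (SD, n = 13 and 12), and the difference went from -0.0191 to -0.00889 percentage points without sedentary library 7. The miR-29 family, abundant in many tissues, took 0.000286% ± 0.00103 and 0.00706% ± 0.0166, under the same doubt about entries emptied before the table was made. The trained share came from 1 count in library 6, and the difference went from -0.00677 to -0.00445 without sedentary library 3 and to -0.00280 without sedentary library 32. Values close to 0 depended on the scaling, and let-7b-5p, miR-26a-5p, miR-127-3p, miR-30a-3p and miR-181b-5p changed sign under at least 1 other scaling.

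Markers of other cells were measured as a check on the preparations. miR-451-5p, the most abundant miRNA of red cells, had 0 counts in all 25 libraries, as had miR-144, with the same limit on what a 0 shows. The erythrocyte list held 2.21% ± 1.29 of counts in trained (SD, n = 13) and 3.04% ± 1.08 in sedentary rats (SD, n = 12), nearly all from miR-486. The leukocyte list held 0.268% ± 0.207 and 0.512% ± 0.416, with 3 tested members, all negative and 0 passing (camera adjusted p = 0.511, lowest adjusted p = 0.578 adjusted over the list alone), and miR-142-3p, miR-223-3p and miR-155-5p were at 0 counts in the table. The smooth muscle list held 2.30% ± 0.722 and 3.21% ± 1.63, mostly miR-143-3p. The endothelial list held 1.13% ± 0.446 and 1.73% ± 1.32, and miR-126a-3p within it had a log2 fold change of -0.040 (SE 0.39). Fibroblast and connective tissue miRNAs held 0.824% ± 0.378 and 1.10% ± 0.793, with 3 tested members, 1 positive and 2 negative, and 0 passing (camera adjusted p = 0.648, lowest adjusted p = 0.234 adjusted over the list alone). The list for liver, brain and pancreas held 0.650% ± 0.407 and 0.520% ± 0.207, mostly miR-128-3p, its only tested member. The liver marker miR-122-5p was not at 0, with 1175 counts over all libraries. It reached 10 counts in 6 of 13 trained and 5 of 12 sedentary libraries. None of these differences in mean share passed the threshold (permutation tests, lowest adjusted p = 0.410 over 23 measures).

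As whole profiles, the groups accounted for 5.58% of the variance between libraries (permutational multivariate test, p = 0.104). The number of miRNAs with a count was 109 ± 12.2 in trained (SD, n = 13) and 118 ± 25.3 in sedentary rats (SD, n = 12; permutation test, p = 0.277, adjusted p = 0.410). The difference of -8.81 went to -5.50 without sedentary library 7 and to -5.59 without sedentary library 32, and at equal depth from -8.43 to -5.12 and -5.21. Shannon entropy was 4.60 ± 0.362 bits and 4.83 ± 0.378 bits (p = 0.143, adjusted p = 0.410). The biological coefficient of variation between libraries was 1.16. With that spread, on real counts with the rats regrouped at random, a 2-fold change was recovered for 28.8% of 160 altered miRNAs and an 8-fold change for 76.3%. Among the 25 most abundant miRNAs the shares were 62.5% and 100%. In each of these data sets 24 of the 76 miRNAs were altered at once. The Benjamini-Hochberg adjustment is stricter when fewer miRNAs change, so these shares do not give the recovery of a lone changed miRNA.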

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

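The settings that count near-identical rows once, take rats by title number, or test detection were chosen after the data were seen. No paired analysis was run, since the labels do not pair trained with sedentary rats. The title numbers alternated between the groups in short runs, and blocks of neighbouring numbers were not tested. 0 miRNAs were called in 15 of 16 other settings (lowest adjusted p 0.169 to 0.952), in 25 of 25 settings without a library, with Fisher's exact test of detection, and among rats numbered 1 to 13 or 14 to 32. The exception was no filter, with 66 calls; their counts in few libraries are weighed under the other observations, and miR-1-3p and miR-3571 were then past the threshold at 0.73. When each library was left out in turn, the number at an unadjusted p under 0.05 ranged from 0 without sedentary library 30 to 8 without sedentary library 29. Over the other settings it reached 14 of 76 with limma-voom and 82 of 260 with no filter. List tests gave 0 calls in their 4 other settings (fry lowest adjusted p 0.339) and composition tests in their 27, and the profile test had its lowest p, 0.0988, with near-identical rows counted once. miR-148a-3p was at 0.63 to 1.01 without a library (p 0.00145 to 0.0578, adjusted p 0.106 to 0.983) and at 0.46 to 0.91 in the 16 other settings, but at -0.034 among rats numbered 1 to 13 and 1.25 among those numbered 14 to 32. Its unadjusted p rose above 0.05 without sedentary library 30 (p = 0.0578), with total counts only (p = 0.107) and with 1 surrogate variable (p = 0.128). Scaling by DESeq2 size factors moved the median log2 fold change from -0.0081 to -0.16, and scaling by total counts to -0.29. Of 46 named miRNAs, 30 kept their sign over the 16 other settings and the 25 without a library, and 20 did so when the ranges of title numbers were included. None of the sign changes was past the threshold (lowest adjusted p 0.777), and their cause was not tested beyond the shifts of scale. With total counts only, values were -0.15 for miR-3557-5p, miR-378a-3p and miR-26a-5p, -0.16 for miR-378b, -0.29 for miR-133a-3p, miR-133b-3p and miR-133c, -0.18 for let-7b-5p, -0.22 for miR-181b-5p and -0.10 for miR-127-3p. With the DESeq2 test and with its size factors alike, miR-133a-3p and miR-133c were at -0.17, miR-133b-3p at -0.16 and miR-30a-3p at 0.057, while let-7b-5p was at -0.074 and -0.075 and miR-181b-5p at -0.066 and -0.070. With no filter, miR-133a-3p and miR-133c were at -0.061, miR-133b-3p at -0.057 and miR-30a-3p at 0.092. With limma-voom, miR-126a-3p was at 0.015, let-7b-5p at -0.11 and miR-181b-5p at -0.65. With limma-trend at pseudocounts of 1 and 0.5, let-7b-5p was at -0.18 in both, miR-30a-3p at 0.16 and 0.24 and miR-181b-5p at -0.30 and -0.29. With the upper quartile, let-7b-5p was at -0.090, miR-30a-3p at 0.060 and miR-127-3p at -0.042. With 10 counts in at least 12 samples, miR-126a-3p was at 0.011, miR-30d-5p at 0.020 and miR-30a-3p at 0.025. Without the most abundant miRNA they were at 0.0017, 0.065 and 0.036, and with near-identical rows counted once at 0.044, 0.070 and 0.040. That last setting also moved the difference in share to 0.376 percentage points for let-7 and miR-98 and 0.000283 for miR-181. It moved the difference from 2.38 to 3.91 for the muscle-enriched list and from 1.38 to 2.58 for the mitochondrial list. For the endurance list it went from 2.59 to 4.31, and for total counts from 8257 to 3197. With 1 surrogate variable, miR-206-3p was at -0.0094, miR-107-3p at 1.11 and miR-30d-5p at 0.12. With the title number as covariate, miR-126a-3p was at 0.053, let-7b-5p at -0.0071 and miR-127-3p at -0.0025, and with the total count miR-127-3p was at -0.028. Among rats numbered 1 to 13, 16 of 45 tested named miRNAs changed sign: miR-148a-3p as above, miR-3596d and let-7f-5p at -0.18, miR-199a-3p at -0.10, miR-486 at 0.055, miR-3557-5p, miR-378a-3p and miR-378b at -0.22, let-7i-5p at -0.38, miR-146b-5p at 0.58, miR-10a-5p at 0.26, miR-30d-5p at 0.27, miR-30a-3p at 0.72, miR-181b-5p at -0.33, miR-27b-3p at -0.041 and miR-92a-3p at 1.21. Among those numbered 14 to 32, 6 of 45 did: miR-133a-3p, miR-133b-3p and miR-133c at -1.11, miR-107-3p at 1.07, let-7b-5p at -0.16 and miR-143-3p at 0.10. Without the shallowest library (12181 counts), miR-378b was at -0.012, miR-30d-5p at 0.063 and miR-30a-3p at 0.062. Leaving out each library gave -0.19 to 0.18 for miR-3557-5p and miR-378a-3p, -0.21 to 0.17 for miR-378b, -0.34 to 0.52 for miR-133a-3p, miR-133b-3p and miR-133c, -0.28 to 0.24 for miR-107-3p, -0.19 to 0.093 for miR-126a-3p, -0.15 to 0.13 for let-7b-5p and -0.24 to 0.0059 for miR-143-3p. It gave -0.14 to 0.14 for miR-30d-5p, -0.25 to 0.23 for miR-30a-3p, -0.22 to 0.46 for miR-181b-5p and -0.19 to 0.26 for miR-127-3p. The difference in total counts then ranged from -1296 to 17940, in the let-7 share from -0.428 to 0.296 and in the miR-181 share from -0.0132 to 0.0108 percentage points. Of 2825 values above 0 in the count table, 694 were under 10 counts, where counting error is large. Differences in share moved by over 1.5 times without a single library for the muscle-enriched list (3.59 percentage points without sedentary library 29), endothelium (-0.340 and -0.370 without sedentary 30 and 32), fibroblasts (-0.117 and -0.178 without sedentary 4 and 7), liver, brain and pancreas (0.0356 without trained 26), miR-17~92 (-0.0882 without sedentary 15) and the Dlk1-Dio3 cluster (-0.317 without sedentary 3).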

Other observations

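The splits of the main and list tests, the tests of near-identical rows, all tests of miR-106b-3p and the split count of miRNAs at an unadjusted p in the numbering test were chosen after the results they concern were seen. The splits without a filter, and the split count for the call of miR-150-3p, were set out before they were run.

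Depth and profile followed the title numbers in trained rats. The 6 trained libraries numbered 1 to 13 had totals of 26793 to 43510 and scores of -7.81 to -3.05 on the first principal component (19.4% of variance), against 72553 to 202388 and 1.59 to 17.0 in the 7 numbered 14 to 27. Yet the shallower libraries held more miRNAs at 10 or more counts, 77 to 110 against 58 to 86. In sedentary libraries the relation of log10 total to number was weak (Pearson r = -0.0103, permutation p = 0.977, adjusted p = 0.977, Spearman rho = -0.126, permutation p = 0.701, adjusted p = 0.701, n = 12, and r = -0.307 without the 2 farthest numbers, 1 of 8 relations computed). Their first component against number had r = 0.337 (permutation p = 0.285, adjusted p = 0.456) and rho = 0.420 (permutation p = 0.175, adjusted p = 0.269), and r = 0.784 without the 2 farthest numbers. The number tested as a term beside the group gave 0 of 76 miRNAs called and 9 at an unadjusted p under 0.05 (edgeR).

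In a test of whether the group difference itself changed between numbers 1 to 13 and 14 to 32, 1 of 76 miRNAs passed, miR-150-3p, the passenger arm of a lymphocyte miRNA (edgeR adjusted p = 0.0211), and 7 had an unadjusted p under 0.05. It reached 10 counts in 5 of 6 trained and 2 of 6 sedentary rats numbered 1 to 13, and in 1 of 7 trained and 5 of 6 sedentary rats numbered 14 to 32. With the numbering redrawn within each group, 2 of 100 splits gave as many calls, the real one included, and the highest other split gave 2. The splits did not repeat the choice of the boundary from the totals, so they do not decide whether chance explains that call. 5 of 100 splits gave 7 or more miRNAs at an unadjusted p under 0.05 (highest other 10), so chance is not excluded for their number. The boundary at 13 was picked from the trained totals, and the sources used here do not say what the numbering stands for, so it stays open whether it marks a batch. Trained libraries were mostly shallower than sedentary ones at numbers 1 to 13 and mostly deeper at 14 to 32. The test therefore does not separate number from depth.

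Without a filter on low counts, 66 miRNAs passed the edgeR test, 26 higher and 40 lower in trained rats. This may reflect miRNAs counted in few libraries. 2 of the 66 were among the 76 tested miRNAs, the median called miRNA had counts in 1 library, and 63 reached 10 counts in at most 4. Regrouping the rats gave as many calls in 42 of 100 splits, with up to 80, so chance is not excluded. The pair that also passes the filter, miR-1-3p and miR-3571, which share their counts, was matched by 9 of 100 splits calling at least 2 such miRNAs, with up to 5. With the filter, a count of 0 calls is reached by 100 of 100 splits by construction, for miRNAs (highest other 1) and for lists (highest other 2), so these comparisons say nothing about chance. In 75 of 100 splits at least 1 miRNA had an unadjusted p under 0.05 (highest other 8), so chance is not excluded for miR-148a-3p.

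Some near-identical rows are consistent with the same reads being entered more than once. Pairs were picked for differing by at most 10%, so the summed difference of each pair was set against independent sampling of equally abundant RNAs within that tolerance (exact test, Bonferroni adjusted over 17 pairs). 12 pairs were closer than that (highest adjusted p 0.00185, and 0.0182 when each library was left out), and 4 of them were identical in every library compared. This argues against separate RNAs sampled independently for these 12. For the other 5 pairs neither explanation is decided. Among them, miR-409a-3p with miR-409b had an adjusted p of 0.0290, which rose to 0.159 without trained library 13 and to 0.0534, 0.106, 0.0776 and 0.185 without sedentary libraries 4, 11, 30 and 32. Of the 17, 12 had overlapping precursors in GRCr8, 4 had separate ones and 1 had no locus for a member. Of 14519 other pairs of rows with known loci, 7 had different precursors that overlap. How the authors' counting treated strand and reads with several matches stays open, and no biological explanation was tested.

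miR-106b-3p, from the miR-106b, miR-93 and miR-25 cluster within the gene Mcm7, reached 10 counts in 9 of 12 sedentary and 1 of 13 trained libraries (Fisher's exact test, two-sided, p = 0.000983). Over the 122 miRNAs tested the adjusted p was 0.1199, so chance is not excluded. The contrast was weaker for any count, in 9 of 12 sedentary and 4 of 13 trained libraries (p = 0.0472, adjusted p = 0.962 over 139 miRNAs). It was the same for 3 or more counts at equal depth (p = 0.000983, adjusted p = 0.115 over 117 miRNAs). Without a filter it passed the edgeR test (log2 fold change -3.91, adjusted p = 0.0157), the setting in which 42 of 100 splits gave as many calls. Lower read totals are argued against, since 5 trained libraries under 10 counts had totals above 94358, the median of the sedentary libraries at 10 or more. Counts here are of reads, so totals do not measure how many molecules were sampled. A smaller sample of molecules stays open. miR-25-3p of the same cluster did not go the same way, at 10 or more counts in 9 of 13 trained and 6 of 12 sedentary libraries. miR-93-5p was in 0 trained and 1 sedentary library. The guide arm miR-106b-5p, miR-93-3p and miR-25-5p were at 0 counts in all 25. Only 1 other arm could thus be compared, and entries may have been emptied before the table was made. A fall of the whole cluster is therefore not decided.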
